A study of Mus musculus with 2 samples.

How the data were processed

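The data were 2 single-cell libraries of CD45-sorted brain cells from C57BL/6J mice, 1 from mice on a control diet and 1 from mice on a high-salt diet, with the group of each library taken from its treatment label. Both samples also carry the word mock in their titles, which the labels do not explain. Per the labels' protocols, mice aged 4 weeks were fed either diet for 4 weeks, brain cells were separated on a Percoll gradient, CD45-positive cells were sorted by flow cytometry, and libraries were made with the 3' v3 chemistry of the 10x Chromium system. The deposited values are whole-number UMI counts per gene and barcode, before any choice of cells, over 31053 genes and 6794880 barcodes per library. Per the submitters' processing notes, Cell Ranger and the mouse assembly mm10 were used, and the version of Cell Ranger and the gene annotation are not given in the sources used here. The gene and barcode lists were the same in both libraries. Symbols shared by more than 1 gene ID, 35 in number, were kept apart by ID. Genome positions came from the GENCODE annotation of the same assembly, in which 31011 of the 31053 gene IDs were found.

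Cells were barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. In the control diet library 4342 barcodes passed the UMI minimum, 4337 also the gene minimum and 4282 also the mitochondrial limit. In the high-salt diet library these numbers were 4202, 4195 and 4147. Doublets were scored by the share of simulated doublets among the nearest neighbours of each cell. The automatic threshold marked 0.374% and 0.265% of cells, too few to be taken as working, so the preset rule was used in its place and the top-scoring 0.8% of cells per 1000 cells was removed, 147 cells of the control diet library and 138 of the high-salt diet library. When 40 doublets of a microglia-like and a T cell-like cell were made from the control diet library, 16 of them scored among the 139 that would be removed, so doublets of this kind remain in part. The cells kept held 82.5% and 84.6% of each library's UMIs. The median mitochondrial share was 2.36% and 2.26%.

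Cells of both libraries were clustered together on log counts per 10000 with 2000 variable genes, 30 principal components, a shared-nearest-neighbour graph of 20 neighbours and the Leiden algorithm at resolution 1, without integration. This gave 19 clusters, of which 12 were microglia-like. Clusters were named from 22 marker lists of brain immune and other brain cells. The class of a cluster was the list with the largest share of markers at 50 CPM or more and at 25% or more of the highest cluster. Its 10 leading genes by fold, with 10 CPM added, were then taken against clusters of other classes. A cluster was left unnamed if under 3 markers were detected, if these genes held more markers of another class, or if they held as many and the share of the best list was under 2 times that of the next. It was also left unnamed if its UMI median was under 1/3 of the library median with no own marker leading, or if its leading genes against all other cells held markers of another class and none of its own. The marker lists were fixed in advance, and this way of scoring them was settled after the clusters had been seen. All microglia-like clusters were pooled. Their leading genes against all other cells included heat shock genes in cluster 2, NF-kB targets and early genes in clusters 3 and 8 and interferon-induced genes in cluster 12, so the sizes of those clusters were not compared between the libraries. Clusters 7 and 9 had low depth, with medians of 2342 and 1562.5 UMIs, and together held 400 control diet cells and 273 high-salt diet cells.

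With 1 library per diet no test was run and no p-value was computed. Cells are not replicates. Shares are given with exact Clopper-Pearson 95% intervals and ratios of shares with exact conditional binomial intervals. For gene values, deposited counts were summed over the cells of a class, divided by the class total to give CPM, and expressed as the log2 ratio of high-salt diet over control diet, with the exact conditional interval for 2 Poisson counts and no pseudocount. All of these intervals cover counting error only, not differences between animals, preparations or cells. The design set a minimum of 100 cells per library for a class to be compared, which only microglia-like cells passed. T cell-like cells and the pooled lymphocyte-like cells were compared in addition, with a minimum of 50 cells.

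The rule for the genes that the text names took the 12 largest and 12 smallest ratios in microglia-like cells. It ran over genes with at least 50 CPM in either library, at least 50 UMIs, an interval excluding 1 and a level of at least 10% of that in the gene's highest class, which keeps out genes whose UMIs come mainly from free RNA. Ribosomal protein, mitochondrial, haemoglobin, sex-linked genes and gene models named Gm or Rik were left out of it. For T cell-like cells the 5 largest and 5 smallest were taken. A further 14 genes were named in microglia-like cells whatever their ratio, and up to 4 members of each list described. Genes outside these rules (Spp1, Csf1, H2-Ab1, Ddit4, Srxn1, Ttr, Il17a and the further T cell-like examples) were chosen after their values were seen.

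The 24 gene lists covered microglial states, interferon, antigen presentation, inflammation, stress, osmotic response, metabolism, the cell cycle, T cell programmes and sex-linked genes. A member was measured with at least 20 UMIs over both libraries and 10 CPM in either. Lists with at least 5 such members were given a median log2 ratio, an interval from 1000 Poisson draws of the counts, and the percentile of the median among 10000 random lists of the same size drawn from 20 bins of expression. A count of members beyond 1.5-fold is a statement of size. For shares of cells and shares of UMIs per cell, cells were thinned at random to 2000 UMIs and shallower cells were left out. The lists, the markers, the cell filter and the rules above were fixed before the data were examined, except where stated.

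The ratio and list steps were tested on simulated Poisson counts for the microglia-like comparison. The interval held the simulated ratio in 95.5% of 12117 genes. Of 50 genes changed 1.2-fold, 98% had an interval excluding 1 on the right side, and so did 100% of 50 genes at each of 1.5-fold, 2-fold and 4-fold. Of 100 random lists of 20 unchanged genes, 98% fell inside the central 95% of matched lists. The simulated counts were Poisson, as the intervals assume, so this checks the code and not the spread between cells or libraries.

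Alternatives tried were a minimum of 500 UMIs and 250 genes, a minimum of 2000 UMIs and 1000 genes, a mitochondrial limit of 5%, doublets kept, Leiden resolution 0.5 and 2, each library clustered alone, class totals without mitochondrial and ribosomal protein genes, scaling by the median ratio, cells weighted equally, a background profile from barcodes with 10 to 100 UMIs subtracted, thinned cells, other CPM minimums for list members, and no rule on the highest class. The background share of microglia-like UMIs, estimated from markers of other classes, was 4.46% in the control diet and 2.39% in the high-salt diet library. It is a median over 61 and 67 marker genes. The marker lists hold genes that microglia-like cells carry themselves, such as Xbp1 (200 and 210 CPM). Ttr alone, at 30.2 and 50.6 CPM against 1638 and 2694 CPM in the background, gives a similar share in both libraries. The difference in the estimate is therefore uncertain. Added after the data were seen were another random seed, a further round of clustering, all lymphocyte clusters pooled, microglia-like cells without some clusters, and T cell-like cells without single cells. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.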

Results

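Single-cell RNA sequencing was carried out on immune cells from the brains of C57BL/6J mice that had been given a control diet or a high-salt diet. Feeding began when the mice were 4 weeks old and lasted 4 weeks. Cells were separated from brain tissue on a Percoll gradient, sorted by flow cytometry for the pan-leukocyte surface protein CD45, and captured in droplets with a 3' library chemistry that tags each transcript with a unique molecular identifier (UMI). The data were 1 library per diet. How many animals went into each library is not given in the sources used here, and no difference between the diets has a replicate check. The control diet library held 28933351 UMIs and the high-salt diet library 26665539 UMIs. After filtering, 4135 cells with a median of 5491 UMIs and 2199 genes were kept for the control diet, and 4009 cells with a median of 5351 UMIs and 2124 genes for the high-salt diet. The comparison asked how a high-salt diet relates to the make-up and the gene expression of CD45-sorted brain cells.

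Microglia-like cells made up most of both libraries, and lymphocyte-like cells took a larger share of the high-salt diet library. T cell-like cells were 1.43% of the control diet cells (59 cells, exact Clopper-Pearson 95% interval 1.09 to 1.84%) and 2.52% of the high-salt diet cells (101 cells, 2.06 to 3.05%), a ratio of shares of 1.77 (1.27 to 2.48). NK cell-like cells were 0.774% (32 cells) and 1.30% (52 cells), a ratio of 1.68 (1.06 to 2.69). B cell-like cells were 0.435% (18 cells) and 0.649% (26 cells), and their ratio of 1.49 had an interval from 0.786 to 2.88 that included 1. Over these 3 lymphocyte classes together the share was 2.64% in the control diet library and 4.47% in the high-salt diet library, a ratio of 1.69 (1.33 to 2.17). Intervals here and in the rest of the text cover counting error only.

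Microglia-like cells accounted for 3885 cells, 94.0% (93.2 to 94.7%), of the control diet library and 3667 cells, 91.5% (90.6 to 92.3%), of the high-salt diet library. These cells carried P2ry12, a purinergic receptor of resting microglia, at 3367 and 3181 CPM (counts scaled by the UMI total of the class), and Tmem119 at 2179 and 2130 CPM. The ratios of the myeloid classes outside microglia had intervals that included 1. Classical monocyte-like cells were 1.04% and 1.25%, with a ratio of 1.2 (0.782 to 1.85), and their leading genes held the cycling gene Mki67 and the basophil gene Prss34 beside Plac8. Neutrophil-like cells, led by S100a8 and S100a9, were 0.435% and 0.374%, with a ratio of 0.860 (0.403 to 1.81). A cluster led by MHC class II genes, Cd209a and Pf4 held markers of both border-associated macrophages and dendritic cells and stayed unnamed. It was 1.79% and 2.0% of the cells, with a ratio of 1.12 (0.803 to 1.55).

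A small choroid plexus or ependymal-like class, led by the thyroid hormone carrier gene Ttr, held 6 cells of the control diet library and 18 of the high-salt diet library, a ratio of 3.09 (1.18 to 9.52). Ptprc, the gene of CD45, had 0 UMIs in the 6 control diet cells and 1 UMI in the 18 high-salt diet cells of this class. The CD45 sort decides which cells could be seen, so shares are shares of sorted and filtered cells and not of the brain.

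**Figure D1:**
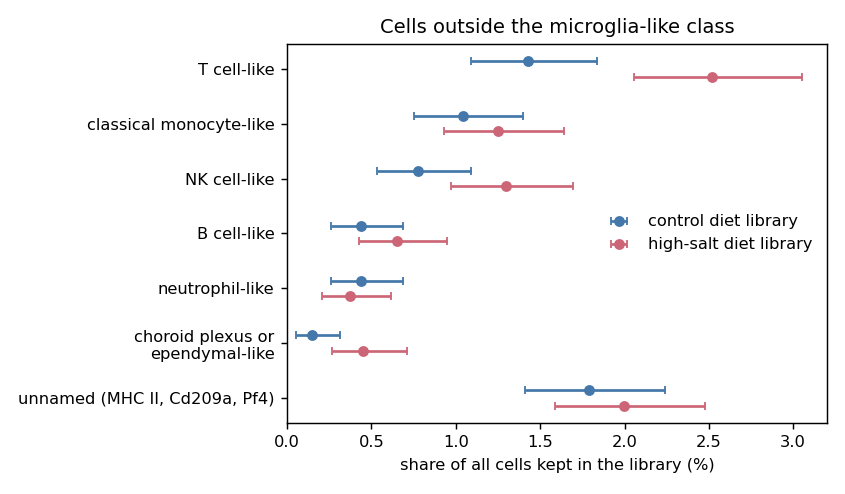
Share of all kept cells (%) in each class outside the microglia-like class, with exact 95% Clopper-Pearson intervals, for the control diet (blue) and high-salt diet (red) libraries. T cell-like cells stood at 1.43% and 2.52%, while the neutrophil-like intervals overlapped.

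Within microglia-like cells, transcripts of NF-kB targets, among them Ccl2 and Il1a, and of the early stress response were higher in the high-salt diet library. Ccl2, a chemokine that draws monocytes, stood at 159 CPM in the control diet library and 300.4 CPM in the high-salt diet library, 1.89-fold higher (log2 ratio 0.92, counting interval 0.86 to 0.98). Il1a, the gene of interleukin 1 alpha, stood at 210.0 and 350 CPM, 1.67-fold higher (log2 ratio 0.74, 0.68 to 0.79). The small heat shock protein gene Hspb1 was 1.83-fold higher, at 114 and 209 CPM. In the opposite direction, Sult1a1, a sulfotransferase, stood at 121 and 81.3 CPM, a ratio of 0.671 (log2 ratio -0.57, -0.67 to -0.48).

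The microglia-like sums rested on 21477001 UMIs in the control diet library and 19804335 UMIs in the high-salt diet library. Most genes lay close to a ratio of 1. Of the 3264 genes with at least 50 CPM in either library, 94.8% had a log2 ratio within 0.2 of 0, and the median was -0.02. The rule set by size picked 12 genes on each side. On the higher side, after Ccl2 and Hspb1, came the cell surface proteoglycan gene Sdc4 (log2 ratio 0.82, 0.70 to 0.94), Il1a, the stress cytokine gene Gdf15 (0.64), the heat shock co-chaperone gene Dnajb1 (0.61), the AP-1 subunit gene Fosb (0.57) and Ifrd1 (0.57). They were followed by Marcksl1 (0.56), the phosphatase gene Dusp1 (0.56), the NF-kB inhibitor family gene Nfkbid (0.55) and Rrad (0.53). On the lower side, after Sult1a1, came the cyclin D3 gene Ccnd3 (-0.36), Pnpla7 (-0.35), the potassium channel gene Kcnk6 (-0.31), the histone gene Hist1h2bc (-0.31), Degs1 (-0.30), Eif4ebp2 (-0.30), Cnppd1 (-0.30), Bcl9l (-0.27), the glucocorticoid-induced gene Tsc22d3 (-0.27), Mrpl18 (-0.26) and BC004004 (-0.25).

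Positions are given for the 4 genes at the top of the higher side and for Sult1a1 and Tsc22d3 from the lower side. In the mm10 assembly, Ccl2 (ENSMUSG00000035385) is annotated on chromosome 11 from 82035571 to 82037453 on the plus strand. Hspb1 (ENSMUSG00000004951) lies on chromosome 5 from 135887919 to 135889563, plus strand, and Sdc4 (ENSMUSG00000017009) on chromosome 2 from 164424247 to 164443887, minus strand. Il1a (ENSMUSG00000027399) is on chromosome 2 from 129299610 to 129309972, minus strand. Sult1a1 (ENSMUSG00000030711) is on chromosome 7 from 126672865 to 126676432, minus strand, and Tsc22d3 (ENSMUSG00000031431) on chromosome X from 140539528 to 140600659, minus strand. All are annotated as protein-coding genes, and 3' counts do not separate their exons or isoforms.

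**Figure D2:**
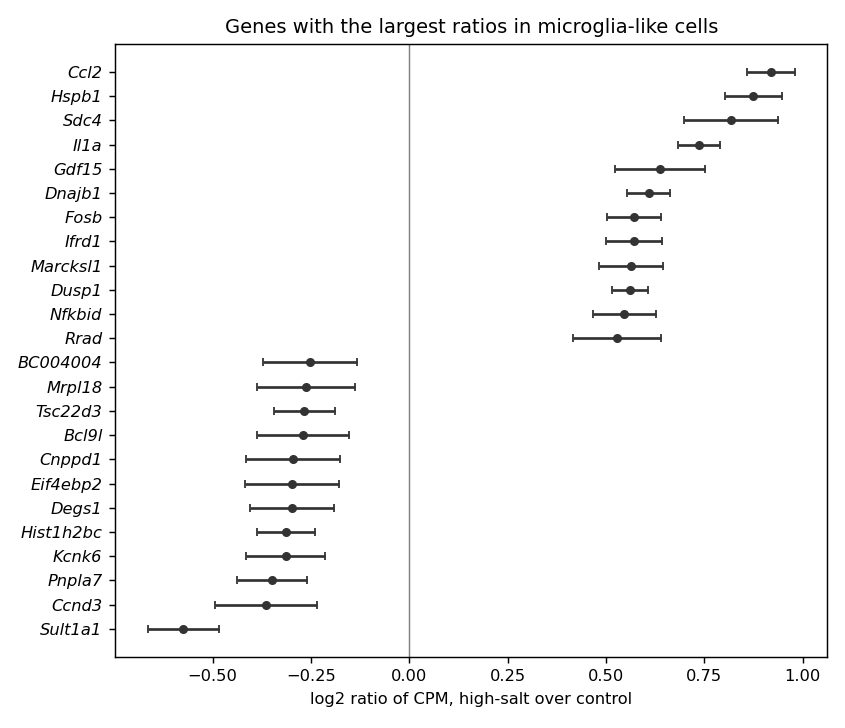
Log2 ratio of CPM (high-salt diet over control diet) in microglia-like cells for the 12 genes with the largest and the 12 with the smallest ratio, with 95% counting intervals as bars. Ratios run from 0.92 for Ccl2 to -0.57 for Sult1a1, with 1 library per diet.

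Genes that had been selected in advance without regard to size gave a mixed picture. The cytokine genes Tnf (143 and 200.4 CPM, log2 ratio 0.48) and Il1b (120 and 173 CPM, 0.52) and the early gene Fos (829 and 1098 CPM, 0.41) were higher in the high-salt diet library. The salt-responsive kinase gene Sgk1 stood at 548 and 605 CPM (0.14, 0.11 to 0.18), and Nfat5, the transcription factor of the osmotic response, at 99.5 and 104 CPM (0.06, -0.03 to 0.15). Among microglial identity genes, the log2 ratio was -0.08 for P2ry12, -0.03 for Tmem119 and 0.03 for Cx3cr1. Ptprc stood at 256 and 258 CPM (0.01). The interferon-induced genes Isg15 (-0.09, -0.25 to 0.06) and Ifit3 (0.24, -0.01 to 0.48) had intervals that included 0. H2-Aa (9.82 and 5.81 CPM) had a log2 ratio of -0.76, Cd74 of -0.16 and Apoe of 0.08, and the direction of each turned under another mitochondrial limit, depth or weighting of cells. A marker of another cell type was higher alongside the stress genes. Ttr, the choroid plexus transcript, stood at 30.2 CPM in control diet and 50.6 CPM in high-salt diet microglia-like cells. In barcodes with 10 to 100 UMIs, taken as free RNA, Ttr stood at 1638 and 2694 CPM. It was also higher in T cell-like cells (25.1 and 46.7 CPM), though not in B cell-like cells (3 and 0 UMIs). Free RNA may thus account for it, and it is not read as a change in microglia-like cells.

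Of the fixed gene lists, the one of NF-kB targets and inflammatory cytokines stood farthest from 0 in microglia-like cells. Of its 22 measured members, 21 were higher in the high-salt diet library, and 5 of these by more than 1.5-fold. The median log2 ratio was 0.40 (counting interval 0.36 to 0.43), at percentile 100 of 10000 random lists matched on expression, as a description of these libraries. Besides Ccl2 and Il1a, the neutrophil chemokine gene Cxcl2 (24.4 and 56.2 CPM, log2 ratio 1.21) was among the highest. Cxcl2 was higher still in other cell classes, and so is outside the rule for the 24 genes. It was seen in 3.01% and 3.49% of the unthinned microglia-like cells. Cxcl2, Ccl2 and Ccl7 of this list were among the leading genes of border-associated macrophage-like cells in a further round of clustering. Whether stray cells or free RNA added to their values was not tested. The list of immediate early and stress genes had 29 measured members, of which 29 were higher, with a median of 0.28 (0.26 to 0.31), also at percentile 100. Its largest ratios were those of Dnajb1, Fosb, Dusp1 and the nuclear receptor gene Nr4a1 (0.51). Without the 3 microglia-like clusters whose leading genes came from these lists, a setting added after the data were seen, the NF-kB median was 0.17 and the early-gene median 0.21.

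Lists of protein folding and of antigen presentation on class I molecules were also higher, by less. Of 12 measured genes of the integrated stress and unfolded protein response, 11 were higher, with a median of 0.16 (0.14 to 0.19) at percentile 99.99. The chaperone gene Hspa5 stood at 933 and 1169 CPM (0.33), Ddit3 at 70.9 and 87.1 CPM (0.30) and Sdf2l1 at 171 and 207 CPM (0.27). The exception was Ddit4, a stress- and glucocorticoid-induced gene, at 25.1 and 16.7 CPM (-0.59). Of 17 measured genes of MHC class I presentation, 13 were higher, with a median of 0.11 (0.08 to 0.15) at percentile 99.99. H2-D1 stood at 667 and 777 CPM (0.22), H2-K1 at 625 and 716 CPM (0.20) and H2-Q4 at 41.7 and 55.8 CPM (0.42). These class I genes are near-identical in parts, so counts can be split between them.

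The lists of microglial state had medians closer to 0 than the NF-kB and early-gene lists. Of 20 homeostatic genes, 6 were higher and 14 lower, with a median of -0.03 (-0.04 to -0.02) at percentile 2.11. Their largest ratios were those of Sall1 (-0.12), Fcrls (0.12) and Selplg (-0.11). Of 18 disease-associated microglia genes, 9 were higher and 9 lower, with a median of 0.00 (-0.01 to 0.03) at percentile 59.9. Spp1 (244 and 110 UMIs, -1.03) and Csf1 (708 and 848 UMIs, 0.38) stood farthest from 0 on either side. Spp1 was higher in the unnamed cluster, at 355 and 41.6 CPM (-3.09). Whether free RNA or stray cells carried it into the microglia-like sums was not tested. The type I interferon list had 8 of 14 members higher and a median of 0.04 (-0.01 to 0.11) at percentile 99.2. Cxcl10 stood at 98.6 and 122 CPM (0.31). The MHC class II list had 6 measured members, 5 of them lower, with a median of -0.12 (-0.16 to -0.06) at percentile 1.41. H2-Ab1 was the lowest (405 and 262 UMIs, -0.51, -0.74 to -0.28), and Cd74 and H2-Oa were at -0.16. H2-Ab1 and Cd74 were among the leading genes of the unnamed cluster. There H2-Aa stood at 11456 and 11648 CPM, against 9.82 and 5.81 CPM in microglia-like cells. Whether free RNA or stray cells set the lower values was not tested.

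The osmotic and salt response list had 9 members higher and 9 lower, a median of 0.02 (-0.02 to 0.07) at percentile 96.8. Its highest member, Ccl2, is also on the NF-kB list. Hspa1b stood at 1321 and 1605 CPM (0.28), and the sodium-potassium-chloride cotransporter gene Slc12a2 at 98.7 and 110.0 CPM (0.16). The antioxidant list had a median of 0.04 at percentile 99.5, with 12 of 16 members higher. In it, haem oxygenase gene Hmox1 stood at 204 and 295 CPM (0.53), and Srxn1 at 6.33 and 17.6 CPM (1.48). The inflammasome list had a median of 0.03 (percentile 96.7), with Nlrp3 at 85.7 and 107 CPM (0.32). The glycolysis list had 0.03 (percentile 99.2), with Pfkfb3 at 0.21, and the cell cycle list 0.02 (percentile 89.9), with Hmgb2 at 0.23.

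Of the other lists, mitochondrially encoded genes of oxidative phosphorylation had a median of -0.06 (percentile 1.27), with mt-Nd1 at -0.12 and mt-Nd4 at -0.10. Their nuclear-encoded partners had -0.01 (percentile 83.1), with Ndufc1 at 0.21. The medians were -0.02 for cholesterol and lipid handling (percentile 61.6), where Abcg1 was at -0.19, and -0.01 for phagocytosis and complement (percentile 35.8), where the complement receptor genes C5ar1 and C3ar1 were at 0.31 and 0.17. The lysosome list was at -0.01 (percentile 17.9). The lists of T cell programmes had under 5 members measured in microglia-like cells, and their values are given for T cell-like cells.

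**Figure D3:**
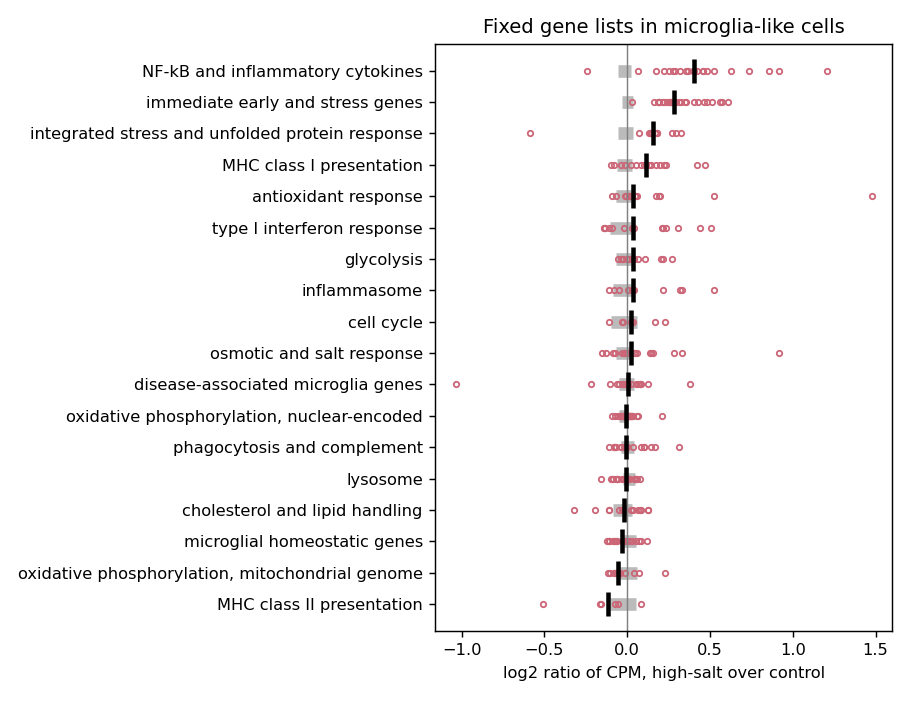
Log2 ratio of CPM (high-salt diet over control diet) in microglia-like cells for the members of each fixed list (open circles), with the list median (black bar) and the range holding 95% of the medians of 10000 random lists matched on expression (grey). The medians of the NF-kB list (0.40) and of the early and stress list (0.28) lie outside the grey range. So do those of MHC class I (0.11) and MHC class II presentation (-0.12) and of the integrated stress list (0.16). The homeostatic, interferon, glycolysis, antioxidant and mitochondrially encoded lists also lie outside it, with medians from -0.06 to 0.04.

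Across single microglia-like cells, the NF-kB list was carried mostly by a minority. Each cell was thinned to 2000 UMIs, which left out 227 shallower cells of the control diet library and 155 of the high-salt diet library. The median share of UMIs from the NF-kB list was then 0.15% in the control diet library and 0.20% in the high-salt diet library, and the 90th percentile was 1.5% and 2.3%. Unthinned, the medians were 0.162% and 0.190%. For the early and stress list the thinned median was 1.75% and 2.10% and the 90th percentile 5.95% and 7.20%. Il1a was seen in 18.2% of the thinned control diet cells (16.9 to 19.5%) and 23.1% of the high-salt diet cells (21.7 to 24.5%), and unthinned in 35.1% and 39.8%. In unthinned lymphocyte-like cells, which should lack it, Il1a was seen in 6.42% and 4.47%, at median depths of 6085 and 5089 UMIs against 5452 and 5309 UMIs in microglia-like cells. Ccl2 was seen in 7.85% and 11.4% of the thinned cells and, unthinned, in 12.4% and 17.8%, against 3.67% and 5.03% of lymphocyte-like cells.

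**Figure D4:**
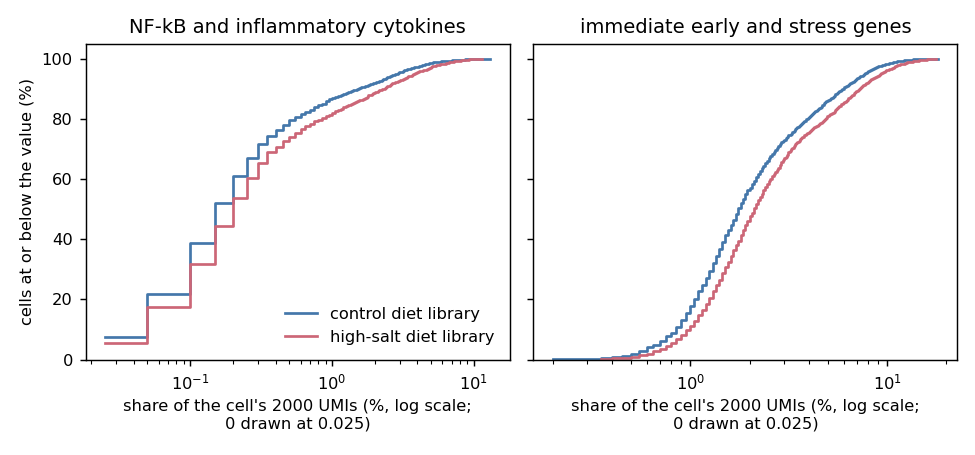
Cumulative share of microglia-like cells (%) by the share of each cell's 2000 thinned UMIs that came from the NF-kB list (left) or the early and stress list (right), on a log axis, for the control diet (blue) and high-salt diet (red) libraries. At the 90th percentile the NF-kB list took 1.5% and 2.3% of a cell's UMIs.

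T cell-like cells of the high-salt diet library carried more transcripts of interferon-induced, cytotoxic and circulation genes for the same number of UMIs. With 59 and 101 cells they were under the preset minimum of 100 cells per library, and were compared with a minimum of 50 cells chosen after the data were seen. Of 25 measured type I interferon genes, 22 were higher, with a median log2 ratio of 1.12 (0.91 to 1.57) at percentile 100 of the random lists. Isg15 stood at 139 and 369 CPM (1.41, 0.99 to 1.84). Ifit1 had 9 and 92 UMIs (2.85, 1.87 to 4.03), Ifit3 had 1 and 79 (5.80, 3.28 to 11.1) and Rsad2 had 3 and 65 (3.94, 2.33 to 6.25). In the opposite direction, Ifitm3 had 26 and 2 UMIs (-4.20, -7.32 to -2.20). The higher UMIs came from few cells. Ifit3 was seen in 1 of 59 and 13 of 101 cells, and 47 of the 65 Rsad2 UMIs came from a single cell. Interferon list genes took over 1% of the UMIs in 2 control diet cells and 9 high-salt diet cells, while the median cell gave 0.115% and 0.132% (thinned to 2000 UMIs, 0.15% and 0.10%). Leaving out the cell with the most list UMIs in each library gave a median of 0.93.

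Cd8b1, a marker of CD8 T cells, was seen in 32.2% of the control diet cells and 48.5% of the high-salt diet cells (376 and 547 CPM), and the gamma-delta receptor gene Trdc in 20.3% and 20.8%, at median depths of 6587 and 5075 UMIs. Whether the mix of T cell types differed was not tested, and the list values are not separated from it. The other T cell programmes differed in direction. Of 13 cytotoxic and T helper 1 genes, 12 were higher, with a median of 0.67 (0.36 to 0.90). The chemokine gene Ccl5 stood at 3520 and 6681 CPM (0.92), Gzmk at 56.9 and 137 CPM (1.26) and the T-bet gene Tbx21 at 18.2 and 74.0 CPM (2.02). Of 8 naive and circulating T cell genes, 6 were higher (median 0.81, 0.43 to 1.18), among them Klf2 (1.09) and Lef1 (1.08). Of 9 residency and exhaustion genes, 7 were higher (0.55, 0.22 to 0.71), with Pdcd1 at 79.7 and 177 CPM (1.15). The 6 measured regulatory T cell genes were lower (-0.61, -1.05 to -0.26), and Tnfrsf4 had 42 and 11 UMIs (-2.43). The T helper 17 list had a median of -0.29 (-0.61 to 0.39). Its Il17a had 10 and 43 UMIs, 34 of these in a single cell, and Csf2 had 111, of which 67 in a single cell, and 29. By size, Rgs16 (2.27, with 40 of 89 high-salt diet UMIs in a single cell) and Isg20 (2.08) also stood on the higher side. Rrad (-2.09), Klf4 (-2.04, with 45 of 122 control diet UMIs in a single cell) and Lmna (-1.67) stood on the lower. Rrad thus had opposite signs in T cell-like and microglia-like cells, and 103 of its 174 control diet UMIs came from a single T cell-like cell.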

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

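The tests in this part were chosen after the patterns had been seen and before the values they rest on, except the ratio from the further round of clustering, which was chosen after its parts had been seen. Further values given beside them were not part of these tests. They include the NF-kB list outside microglia-like cells, single genes in T cell-like cells, and Fkbp5 and Nfkbia. Each diet had 1 library, so no library was compared with others of its group. None of the 18 gene lists with medians in both microglia-like and lymphocyte-like cells had opposite directions with both counting intervals off 0.

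Barcodes with at least 100 and under 1000 UMIs, which the comparisons of the report did not use, are given here because they held microglial transcripts. The alternative with a minimum of 500 UMIs took in some of them. There were 2124 such barcodes in the control diet library, with 1748 UMIs of P2ry12 (2984 CPM), and 795 in the high-salt diet library, with 499 UMIs of P2ry12 (2591 CPM). Barcodes with 10 to 100 UMIs, taken as free RNA, held P2ry12 at 2992 and 2674 CPM, so this level does not set these barcodes apart from free RNA. Their median mitochondrial share was 0.943% in the control diet library and 3.44% in the high-salt diet library. Of the control diet barcodes 289 had over 20% mitochondrial UMIs, and of the high-salt diet barcodes 335 had.

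The early-response and NF-kB genes were higher in microglia-like cells of the high-salt diet library, with list medians of 0.28 and 0.40. A difference in depth was not tested by thinning, since the ratios are already taken per class UMI total. The NF-kB median was 0.43 with every cell thinned to 2000 UMIs, from median depths of 5452 and 5309 UMIs. After the background profile was subtracted the NF-kB median was 0.39. This argues against free RNA as the cause of the NF-kB part only at the estimated shares of 4.46% and 2.39%. Shares of that size could hardly move the median. Activation of cells during dissociation and sorting is possible and predicts higher early genes in lymphocyte-like cells, which went through the same preparation. Their median for the early and stress list was 0.25 (0.13 to 0.32), with 23 of 29 members higher. An effect of the diet on all these cells would give the same, so this value does not separate the 2 explanations. In T cell-like cells Dnajb1, Fosb, Dusp1 and Nr4a1, the largest ratios of this list in microglia-like cells, stood at 0.002, -0.48, 0.07 and -0.02. The list median in T cell-like cells was still 0.25 (0.17 to 0.40). Of its 29 members there 23 were higher, among them Hspa1a (1.27) and Egr1 (1.33). The NF-kB list had a median of -0.00 in T cell-like cells, with 7 of 14 members higher. The NF-kB list had a median of 0.14 (-0.08 to 0.44) in lymphocyte-like cells. In the unnamed macrophage and dendritic cell cluster it had 0.43 (0.27 to 0.54, 19 of 25 members higher). The mix of cell types there was not held fixed. The further round of clustering gave 29 and 42 border-associated macrophage-like cells, led by Ccl7 and Cxcl2 among others. It also gave 24 and 19 dendritic cell-like cells, and an unnamed cluster of 19 and 15 cells led by Il12b and Ccr9. Whether the NF-kB part follows thus stays open. An effect of the diet on these cells stays open as untested, because each diet was prepared as 1 library.

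Lymphocyte-like cells took a larger share of the high-salt diet library, at a ratio of 1.69. A lower recovery of microglia, which would raise every other type alike, is argued against as the whole cause, within counting error: the lymphocyte ratio was 1.53 times (1.08 to 2.17) that of the other immune clusters, and 1.57 times (1.10 to 2.25) in the further round of clustering. The other immune clusters were not alike in that round, since classical monocyte-like cells had a ratio of 1.52 (0.872 to 2.71) and border-associated macrophage-like cells 1.49 (0.909 to 2.49), against 0.817 for conventional dendritic cell-like cells, so a part of the pattern stays open to it. More blood cells left in the vessels could add lymphocytes, and neutrophil-like cells, which would come along, had 0.507 times (0.228 to 1.12) the lymphocyte ratio, too few cells to decide, while haemoglobin UMIs in the cells were 26 and 5. The diet itself stays open as untested.

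Sult1a1, Tsc22d3 and Ddit4 were lower in microglia-like cells of the high-salt diet library, at log2 ratios of -0.57, -0.27 and -0.59. A different time of day at collection could produce this through clock control. The median of 8 measured clock genes of the Per and Dbp arm was -0.16 (-0.21 to -0.08), at percentile 0.06 of random lists, with 7 lower. This median passes the size of 0.15 set in advance while its interval does not. Lower glucocorticoid signalling is possible too. The median of 11 other glucocorticoid-induced genes was 0.00377 (-0.06 to 0.04), at percentile 78.8, with 6 higher. It lies just on the side set in advance as against this explanation, with an interval that includes 0. Among these genes Fkbp5 stood at 39.4 and 25.1 CPM (-0.65), while Nfkbia, which is also an NF-kB target, was at 0.28. The sizes set in advance were for the medians alone. With the intervals neither explanation is decided, and the diet stays open as untested.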

How the results depend on the processing

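The alternatives without the word added were planned. The numbers of cells stayed within 1.5 times, 3891 to 4380 for the control diet and 3788 to 4147 for the high-salt diet. The lymphocyte ratio of shares stayed above 1 in 9 of 9 alternatives (1.68 to 1.91), the T cell-like ratio in 6 (1.69 to 1.90) and the NK cell-like ratio in 7 (1.67 to 1.82). T cell-like values with 500 UMIs, 5% mitochondrial UMIs or each library clustered alone, NK cell-like values with 500 UMIs or separate clustering, and the B cell-like value with 5% were left out, by a rule set after they were seen, because under 50% of the class kept its name in a library. A mitochondrial limit of 5% gave microglia-like shares of 94.9% and 93.0%, and separate clustering gave 87.0% for the high-salt diet. The 5% limit left 66 and 123 lymphocyte-like cells, against 109 and 179 in the main setting, so the shares themselves depend on it. The NF-kB and early-gene medians stayed above 0 in 16 of 16 alternatives. The NF-kB median was 0.43 with thinned cells, and without the clusters led by NF-kB or stress genes (added) it was 0.17. The early-gene median was 0.26 with cells weighted equally and 0.21 without those clusters (added), where the antioxidant median turned to -0.0119. The T cell-like interferon median was 0.91 with cells weighted equally (added). A limit of 5% mitochondrial UMIs turned H2-Aa to 0.42 and Cd74 to 0.14, thinned cells turned H2-Aa to 0.0898 and Apoe to -0.0273, and equal weights turned Apoe to -0.0731. The cause was not tested. Over all alternatives, 428 values of named genes and 259 list medians stayed within their counting intervals, 23 and 25 moved out of them, and 5 and 1 reversed. No paired analysis was possible because each diet had 1 library and no test was run. Of the 24 genes named by size, 22 were named without the rule on the highest class. Counting error limits the classes under 100 cells, and no alternative stands in for a replicate library.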

Other observations

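All clusterings and comparisons in this part were chosen after the data had been seen. A further round of clustering of the 250 control diet and 342 high-salt diet cells outside the microglia-like class split the larger groups. Its T cell-like cluster, led by Cd8a, Trac and Gzmk, held 43 and 79 cells, a ratio of shares of 1.90 (1.29 to 2.82). A cluster led by the gamma-delta T cell receptor genes Tcrg-C1 and Trdc and by Cd163l1 held 13 and 21 cells (1.67, 0.796 to 3.62). A pair of NK cell-like clusters, led by Xcl1 and by Gzma, held 16 and 26 cells (1.68, 0.866 to 3.34) and 14 and 26 cells (1.92, 0.964 to 3.97). B cell-like cells stood at 1.49, and of these 5 lymphocyte clusters the T cell-like cluster had an interval that excluded 1. Classical monocyte-like cells, led by Prss34, Mcpt8 and F13a1, held 23 and 34 cells (1.52, 0.872 to 2.71), against 43 and 50 in the main clustering. A microglia-like cluster, with 12 of 12 markers detected and a median of 10996 UMIs, held 19 and 13 cells. The main shares count these cells outside the microglia-like class, and whether they are doublets was not tested. Border-associated macrophage-like cells, led by Pf4, Ccl7 and Apoe, held 29 and 42 cells (1.49, 0.909 to 2.49). Conventional dendritic cell-like cells, with Cd209a and Ccl17 among their leading genes, held 24 and 19 (0.817, 0.423 to 1.56), and non-classical monocyte-like cells, led by Treml4, held 10 and 8. A cluster led by Il12b, Ccr9, Cd209d and Cox6a2 stayed unnamed and held 19 and 15 cells (0.814, 0.385 to 1.69).

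The unnamed cluster of macrophage and dendritic cell markers held 74 and 80 cells. Of its 29 measured type I interferon genes, 25 were higher in the high-salt diet library, with a median of 0.56 (0.42 to 0.79). The pooled lymphocyte-like cells had a median of 0.66 (0.50 to 0.98), but the pool includes the T cell-like cells, which held 79 of its 80 Ifit3 UMIs and 229 of its 263 Isg15 UMIs in the high-salt diet library. Microglia-like cells had 0.04 for this list. In the unnamed cluster, 37 nuclear-encoded genes of oxidative phosphorylation had a median of -0.31, with 34 lower, and 12 measured cell cycle genes one of -1.03. Differences between these cell groups were not tested, and the cluster holds more than 1 cell type, in a mix that was not held fixed. Its early and stress genes had a median of 0.23 (0.18 to 0.33), and in it Ly6d had 0 and 211 UMIs and Fn1 254 and 11. Ccr9, like Ly6d a plasmacytoid dendritic cell marker of the fixed lists, had 3 and 58 UMIs.

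In lymphocyte-like cells the microglial homeostatic list had a median of -0.59 (-0.75 to -0.47), with 19 of 19 members lower in the high-salt diet library. Selplg, which lymphocytes also express (799 and 707 CPM), was at -0.18, while P2ry12 was at -0.73, Tmem119 at -0.79 and Siglech at -1.08. The background share estimated for microglia-like cells was 4.46% in the control diet library and 2.39% in the high-salt diet library. The Ttr levels did not show this difference between the libraries. P2ry12 was seen in 24.8% of the control diet and 15.1% of the high-salt diet lymphocyte-like cells. The classes were not alike. P2ry12 stood at 170 and 20.9 CPM in NK cell-like cells (34 and 7 UMIs). In T cell-like cells it stood at 173 and 150 CPM (-0.21, -0.66 to 0.25). The list median there was -0.21 (-0.38 to -0.08), with 15 of 17 members lower. Whether free RNA or remaining doublets set these values was not tested.

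In T cell-like cells the MHC class II list had 5 measured members and a median of 2.89, and 95 of the 104 Cd74 UMIs of the high-salt diet library came from a single cell. Other lists there had medians of 0.25 for early and stress genes, -0.00 for NF-kB genes and 0.32 for MHC class I presentation.

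Both libraries held Y-linked transcripts and almost no Xist. Xist had 2 and 2 UMIs, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 2208, 1754, 448 and 444 UMIs in the control diet library and 2126, 1433, 396 and 424 in the high-salt diet library.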
